A study of Xenopus tropicalis with 26 samples.

How the data were processed

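RNA of early Xenopus tropicalis embryos was measured by stranded, polyA-selected sequencing in 26 libraries, 2 in each of 13 groups. Stage, injected reagents and replicate number were read from the labels and the column names. The deltaDBD and E2f1 mRNA columns were matched to the labels by their names, and the level of e2f1 in them was then checked. Per the submitters' processing notes, reads were trimmed with fastp and aligned with STAR 2.7.0e, and genes were counted with featureCounts 2.0.1. Per the file headers, counting was reverse-stranded and by fragment, both mates had to map, chimeric pairs were left out, and fragments mapping to several places were not counted. The deposited gene counts are whole numbers and were used as they stand. Coordinates are those of the file, in the v10 build and 1-based, and gene names are those of the file. Trimming settings and the versions of fastp and deepTools are not given in the sources used here. Coverage tracks were not used here.

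The table held 28778 genes, and 12883 passed the filterByExpr function of edgeR with its default settings. Totals ran from 14071614 to 19032710 counts. At a group total of 3 counts, the floor used for groups with no count, a gene cannot be told from absence, so folds against such groups are given as lower bounds, and groups of 1 to 3 counts have 95% counting intervals of the ratio. Fitted log2 values of genes with no count in a group, interactions included, are no bounds. CPM, counts scaled to library size, used library sizes scaled by trimmed means of M-values (TMM). One quasi-likelihood negative binomial model with 13 group means was fitted to all libraries (edgeR 4.0.16 in R 4.3.3, robust, biological coefficient of variation 3.93%), leaving 13 residual degrees of freedom.

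Before the data were examined, 25 contrasts were set down: stages within wildtype, each injected group against wildtype or against the MO within a stage, E2f1 mRNA against deltaDBD mRNA, the interaction of MO and Cdkn1a mRNA at each stage, and the change of the MO and Cdkn1a effects between stages. P-values were adjusted by the Benjamini-Hochberg method over the tested genes of each contrast, and genes under an adjusted p of 0.05 were called. Lists of genes fixed in advance were tested with camera of limma 3.58.1 at its preset correlation of 0.01 and again with an estimated correlation, adjusted over 450 tests. They were early zygotic genes (59 tested, 3 of them in another list), maternal oocyte genes (56, 5), DNA replication and E2F target genes (64, 4), E2F and RB family (23, 3), mitotic genes (42, 4), p53 pathway (26, 4), apoptosis (28, 2), innate immune and interferon response (21, 0), stress response (27, 1), histones (20, 2), cytosolic ribosomal proteins (73, 0), nuclear oxidative phosphorylation genes (53, 0), RNA polymerase II machinery (48, 1), chromatin regulators (38, 2), Nodal, Wnt, BMP and FGF components (37, 1), and markers of differentiated tissues (6, 1), testis (10, 0) and follicle (3, 1). A list of 26 genes of the mitochondrial genome had none in the table.

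Named genes followed a rule set in advance. e2f1 and cdkn1a were read in every library. In each contrast the 6 largest rises and the 6 largest falls were taken among called genes with a symbol other than a locus number, a mean of 2 CPM or more in the higher group and the same direction in every pairing of libraries. From each list described, up to 4 members with the smallest p were taken, and contrasts with fewer than 3 calls gave the 3 genes of smallest p. Some genes that met the rule are not reported here.

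Genes that changed 2-fold or more in wildtype between stages 6 and 8 were read in stage 7 groups, and those between stages 6 and 7 in stage 8 groups, so that list and contrast share no library. Shares of the wildtype step were slopes through the origin of fitted log2 values, without bounds for genes with no count. These slopes ran over the stage 6 to 8 lists at both stages. They share wildtype libraries with the contrast and were set against simulated unchanged groups. Overlaps of calls were compared with the product of the list sizes over the number of tested genes, adjusted over 84 tests. For pairs with common controls, unchanged groups were simulated in 20 draws.

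The pipeline was tested on simulated data with 200 changed genes. For the MO against wildtype at stage 7 it recovered 73.1, 88.1 and 93.9% of genes changed 1.5-fold, 2-fold and 4-fold and called 9 of 12633 unchanged genes. For Cdkn1a mRNA at stage 8 the shares were 59.7, 83.6 and 87.9%, and for the interaction at stage 8 67.2, 73.1 and 89.4%.

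Alternatives set down beforehand were median-of-ratios size factors, the Wald test of DESeq2 1.42.0, no count filter, a replicate block, only the libraries of the stages compared, e2f1 and cdkn1a left out, and each library left out in turn. For lists they included an estimated correlation, and for the time course a 4-fold threshold. Overlaps were repeated at an unadjusted p of 0.01 and with DESeq2 calls. Leaving stage 8 E2f1 MO replicate 2 aside, a pair of further overlaps, the genes low in morphants at both stages, the share of the wildtype step and the span of chromosome 6 were chosen after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.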

Results

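Messenger RNA of cleavage and blastula stage embryos of the frog Xenopus tropicalis was sequenced in 26 libraries. They form 13 groups of 2 libraries each, so every mean ± SD has n = 2. Wildtype embryos were collected at stages 6, 7 and 8, which lead up to the mid-blastula, when the embryo's own genome becomes strongly transcribed. At stages 7 and 8 there were also embryos given an antisense morpholino oligonucleotide (MO) against E2f1, a transcription factor best known for activating cell cycle genes. Other groups received this MO with E2f1 mRNA, with a form of E2f1 mRNA named deltaDBD (by its name without the DNA-binding domain), or with mRNA of Cdkn1a, an inhibitor of cyclin-dependent kinases, and a last group received Cdkn1a mRNA alone. The gene table held between 14071614 and 19032710 counted fragments per library. Of its 28778 genes, 12883 had enough counts to be tested. The labels do not say that the replicates of a group came from separate clutches, so the p-values measure only the spread between these libraries, which may be technical.

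The injected transcripts were read first, as a check of the labels. e2f1 (chromosome 10, 41691473 to 41704773 in the v10 build) stood at 440 ± 9.2 CPM (counts scaled to library size) in stage 7 wildtype and at 426 ± 17 CPM in stage 7 E2f1 MO embryos. With E2f1 mRNA it reached 3010 ± 36 CPM at stage 7 and 2730 ± 19 CPM at stage 8, and with deltaDBD mRNA 2110 ± 45 and 2050 ± 43 CPM. All 18 libraries without an E2f1 construct lay between 376 and 537 CPM. A morpholino blocks translation or splicing and the labels do not say which, so the e2f1 level checks the injected mRNA and not the knockdown. It does not tell the E2f1 and deltaDBD mRNA groups apart either, which were told by the names of their columns. cdkn1a (chromosome 2, 54652721 to 54677604) was at 3.65 ± 0.36 CPM in stage 7 wildtype. It was at 298 ± 7.8 CPM with Cdkn1a mRNA and at 239 ± 4.7 CPM with the MO and Cdkn1a mRNA at stage 7, and at 286 ± 3.3 and 239 ± 0.92 CPM at stage 8. In the libraries without Cdkn1a mRNA it did not exceed 6.09 CPM.

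**Figure D1:**
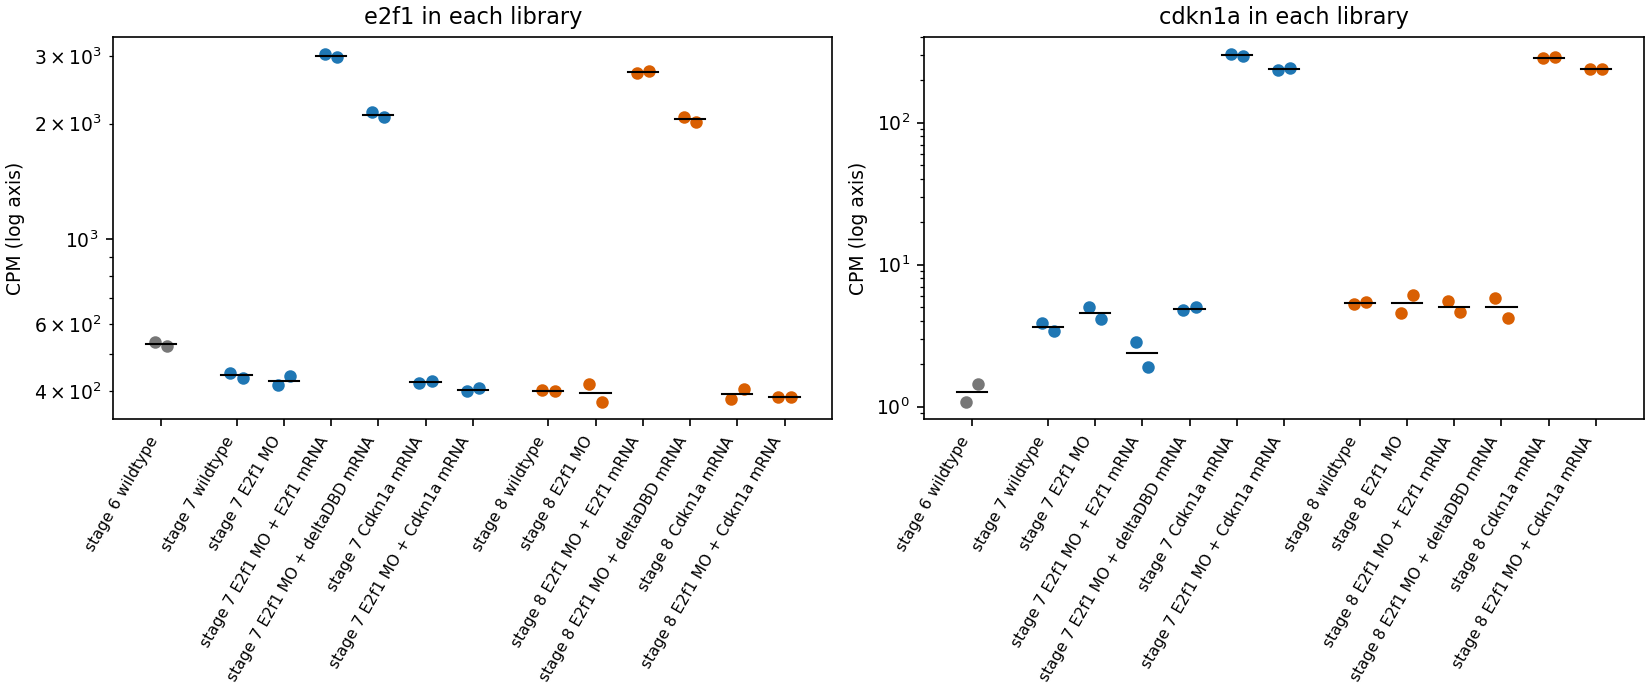
CPM of e2f1 and cdkn1a in each of the 26 libraries, on a log axis; dots are libraries, black lines are the means of 2, and grey, blue and orange mark stages 6, 7 and 8. e2f1 means of 2050 CPM and more occur only with E2f1 or deltaDBD mRNA, and cdkn1a means of 239 CPM and more only with Cdkn1a mRNA.

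Between stages 6 and 7 of wildtype development, a first set of zygotic genes appeared while other transcripts became less abundant in the polyA-selected RNA. Here and below, a change in transcript amount is not told apart from a change in its capture by polyA selection. Nodal ligands and an organizer gene were among the strongest rises: sia2, a homeobox gene of the dorsal organizer, was at 3.0 ± 0.38 CPM at stage 7 against no read at stage 6, at least 31-fold higher (adjusted p = 7.3e-11 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, as for all gene tests below). nodal3.1 and nodal6, ligands of the Nodal family, rose at least 29.5-fold and at least 24.3-fold. The zinc finger gene znf470 rose at least 58.2-fold, and its neighbours on chromosome 6, znf33b and znf350, rose 35.5-fold (counting interval 10.6 to 331) and 34.9-fold (12.5 to 184). The fall was steepest for slc5a5, an iodide transporter gene (log2 fold change −2.13 ± 0.36 SE), followed by aff2 (−1.41 ± 0.28), the complement gene c9 (−1.33 ± 0.29), p2ry1 (−1.31 ± 0.37), the adenylyl cyclase gene adcy8 (−1.30 ± 0.30) and emilin3 (−1.28 ± 0.53). The calls of p2ry1 and emilin3 depended on single libraries: p2ry1 was at adjusted p = 0.052 without stage 7 wildtype replicate 1, and emilin3 at 0.30 without stage 6 wildtype replicate 1 and at 0.28 without stage 7 wildtype replicate 2. In all, 7249 genes changed, 3657 up and 3592 down, and 739 rose and 62 fell by 2-fold or more.

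By the gene lists fixed in advance, 22 of the 59 tested early zygotic genes rose from stage 6 to 7 and 3 fell (adjusted over the list alone, also 22 and 3). Their median log2 fold change was 2.30, or 0.36 with the 28 genes at 0 in one group held at their bound (camera adjusted p = 0.00107, and adjusted p = 0.00479 with an estimated correlation). sox11, a neural transcription factor gene also stored in the egg, rose by 1.1 ± 0.057, and bambi, a BMP pseudoreceptor gene, was among the 3 that fell (−0.52 ± 0.052). Mitotic genes went down together: 27 of 42 fell and 8 rose (adjusted over the list alone, 28 and 8), with top2a (−1.0 ± 0.044), smc4 (−0.72 ± 0.035) and ncapd2 (−0.56 ± 0.031), which act in chromosome condensation, and wee2, an inhibitory kinase of Cdk1 (−0.55 ± 0.031). The mitotic list gave adjusted p = 0.000178, and adjusted p = 0.00393 with an estimated correlation. Of 48 genes of the RNA polymerase II machinery, 32 fell and 9 rose (adjusted over the list alone, 33 and 10; adjusted p = 0.00337, and adjusted p = 0.0232 with an estimated correlation). The elongation kinase genes cdk9 (1.08 ± 0.061) and ccnt2 (0.82 ± 0.055) were among its rises, and gtf2a1 (−0.45 ± 0.032) and tbpl1 (−0.63 ± 0.049) among its falls. Maternal oocyte genes went both ways, 16 up and 29 down of 56 (adjusted over the list alone, 17 and 29; adjusted p = 0.0798). DNA replication and E2F target genes moved both ways, 20 up and 27 down of 64, with dnmt1 at −1.01 ± 0.034, cdc6 at −0.47 ± 0.029, mybl2 at 1.02 ± 0.040 and rpa1 at 1.17 ± 0.063, and the list as a whole did not move (adjusted p = 0.352).

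From stage 7 to stage 8 the zygotic genes rose as a group, 51 of 59 up and 1 down (adjusted over the list alone, 54 and 1). The median was 3.0, or 2.87 with 3 genes at their bound (adjusted p = 2.18e-29, and adjusted p = 9.82e-08 with an estimated correlation). ventx2.2, a ventral homeobox gene, rose from 1.67 ± 0.39 to 33.5 ± 3.0 CPM (4.34 ± 0.15), klf17 by 2.87 ± 0.10, the dorsal signalling gene admp by 5.26 ± 0.21 and the BMP target id3 by 2.55 ± 0.12. Genes first read at stage 8 included tfap2a, an epidermal and neural crest regulator (at least 51.2-fold), the tyrosine aminotransferase gene tat (at least 39.4-fold), fst (follistatin, at least 30.5-fold), chrd.1 (chordin, at least 25.7-fold) and znf750 (at least 25.7-fold), while rhov rose 361-fold (counting interval 80.9 to 17900). Falls included plbd2 (−1.39 ± 0.075), cks2, a Cdk-binding subunit (−1.31 ± 0.13), kif26a (−1.45 ± 0.21), lad1 (−1.35 ± 0.31) and chn2 (−1.21 ± 0.22). adcy8 also fell (−1.33 ± 0.40), but its adjusted p was 0.12 without stage 7 wildtype replicate 2 and 0.078 without stage 8 wildtype replicate 1. Mitotic genes continued down, 23 of 42 against 6 up (adjusted over the list alone, 24 and 7; adjusted p = 1.49e-05, and adjusted p = 0.00166 with an estimated correlation). Altogether 4729 genes changed, 2461 up and 2268 down, of which 339 rose and 42 fell by 2-fold or more.

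Over the whole interval from stage 6 to 8, 8883 genes changed, with 1707 rising and 299 falling by 2-fold or more. znf470 (at least 765-fold), sbk1l (at least 412-fold), ventx2.2 (at least 345-fold), admp (at least 183-fold), ventx2.1 (at least 167-fold) and nodal3.1 (at least 166-fold) had no read at stage 6. The cell cycle genes cks2 (−2.56 ± 0.13) and cdca3 (−2.43 ± 0.097) fell, as did plbd2 (−2.62 ± 0.072), adcy8 (−2.63 ± 0.35), lad1 (−2.47 ± 0.27) and slc5a5 (−2.30 ± 0.36). fbxo43, which encodes an inhibitor of the anaphase-promoting complex in the egg, fell from 539 ± 12 to 126 ± 1.6 CPM. Of the early zygotic genes 52 rose and 3 fell (adjusted over the list alone, 53 and 3), with a median of 6.32, or 4.41 with 28 genes at their bound (adjusted p = 3.83e-12, and adjusted p = 1.22e-05 with an estimated correlation). Lower bounds use a floor of 3 counts over the group, and floors and counting intervals cover counting error only.

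The earliest wildtype risers were clustered in the genome. Of 82 genes that rose 8-fold or more from stage 6 to 7, 29 lay on chromosome 6 (7.33 by its share of tested genes; Fisher's exact test, adjusted p = 3.26e-10). On chromosome 3, which holds nodal5, nodal6, nodal3.1, sia1 and sia2, there were 16 (9.88 by its share, adjusted p = 0.194). Chromosome 2 held 1 (10 by its share, adjusted p = 0.00261). Within the span of chromosome 6 that holds znf470, znf3, znf33a, znf33b and znf350, 23 of 44 tested genes were such risers, and this span was chosen after the result was seen. Fisher's exact test takes genes as independent, which neighbours in 1 span may not be, so its p may be too small. Near-identical copies, which were not looked for, would make single counts there uncertain, as fragments mapping to several places were not counted. All 23 genes were higher in stage 7 morphants than in wildtype (median 2.69), all 23 were lower with E2f1 mRNA than with deltaDBD mRNA at stage 7 (median −4.05), and all 23 were lower with Cdkn1a mRNA at stage 8 (median −2.59).

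**Figure D2:**
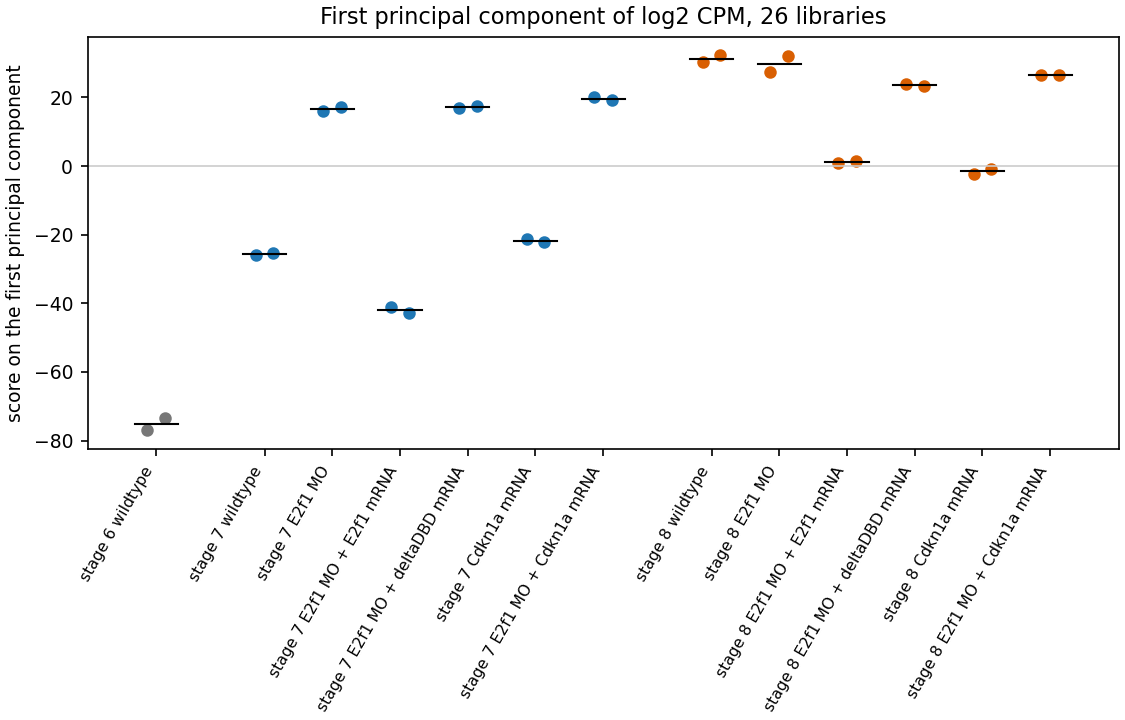
Score of each library on the first principal component of log2 CPM, which held 55.3% of the variance; dots are libraries and black lines group means, coloured by stage. Wildtype moves from −77 and −73.4 at stage 6 over −25.9 and −25.2 at stage 7 to 30.4 and 32.2 at stage 8, stage 7 morphants without further mRNA, with deltaDBD mRNA or with Cdkn1a mRNA lie between 15.9 and 20, stage 7 embryos with Cdkn1a mRNA and no MO at −21.4 and −22.1, and stage 7 embryos with the MO and E2f1 mRNA lie at −41.1 and −42.8.

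The effect of the E2f1 MO was measured against wildtype of the same stage. At stage 7, morphant embryos held more of the zygotic transcripts than wildtype embryos of that stage: 44 of the 59 early zygotic genes were higher and 1 lower (adjusted over the list alone, 52 and 1). The median log2 fold change was 2.15, or 2.1 with 3 genes at their bound (adjusted p = 5.23e-30, and adjusted p = 9.82e-08 with an estimated correlation). tfap2a stood at 2.09 ± 0.01 CPM against no read in wildtype, at least 24.5-fold higher (adjusted p = 1.8e-07). rhov was 152-fold higher (counting interval 33.7 to 7550), the homeobox gene irx1 89.1-fold (27.5 to 835), the growth factor gene fgf8 68.9-fold (15.1 to 3450), the Wnt antagonist gene sfrp2 64.5-fold (14 to 3210) and the neural plate gene foxd4l1.1 43.5-fold (15.8 to 231). ventx2.2 rose from 1.67 ± 0.39 to 21.2 ± 1.6 CPM (3.68 ± 0.16), admp by 4.11 ± 0.24, klf17 by 2.04 ± 0.11 and id3 by 2.01 ± 0.12. In all, 3243 genes differed, 1639 higher and 1604 lower, with 262 higher and 37 lower by 2-fold or more. The count was 1922 without stage 7 E2f1 MO replicate 2 and 1943 without stage 7 wildtype replicate 1.

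Stored transcripts were lower in the polyA-selected RNA of the stage 7 morphants. Of the 56 maternal oocyte genes, 30 fell and 5 rose (adjusted over the list alone, 32 and 7; adjusted p = 1.6e-07, and adjusted p = 0.0274 with an estimated correlation). They include the germ plasm genes grip2 (−1.17 ± 0.060), nanos1 (−0.86 ± 0.070) and ddx25 (−0.58 ± 0.049) as well as fbxo43 (−0.54 ± 0.039). Mitotic genes fell too, 26 of 42 against 5 up (adjusted over the list alone, 26 and 8; adjusted p = 1.72e-06, and adjusted p = 0.000812 with an estimated correlation), with top2a at −0.69 ± 0.045, smc4 at −0.41 ± 0.035, plk1 at −0.37 ± 0.038 and ncapd2 at −0.28 ± 0.031. Genes for the RNA polymerase II machinery were 14 lower and 4 higher of 48 (adjusted over the list alone, 18 and 7; adjusted p = 0.0408, but adjusted p = 0.113 with an estimated correlation). Among DNA replication and E2F target genes, 20 of 64 fell and 9 rose (adjusted over the list alone, 22 and 11), with dnmt1 at −0.70 ± 0.034 and rpa1 at 0.55 ± 0.055. Over all 12883 tested genes, 1604 were lower and 1639 higher. The list was not called as a shift of the whole (camera adjusted p = 0.203), which does not show that its genes were unaffected. The largest single falls were outside these lists: arpc3, an Arp2/3 complex subunit (−1.91 ± 0.14), tmem203 (−1.87 ± 0.19), the signalosome gene cops6 (−1.55 ± 0.12), the inositol phosphatase gene inpp5j (−1.51 ± 0.18) and the prolyl isomerase gene ppia (−1.44 ± 0.070). adcy8 was at −1.34 ± 0.40, with adjusted p = 0.12 without stage 7 E2f1 MO replicate 1 and 0.155 without stage 7 wildtype replicate 2.

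**Figure D3:**
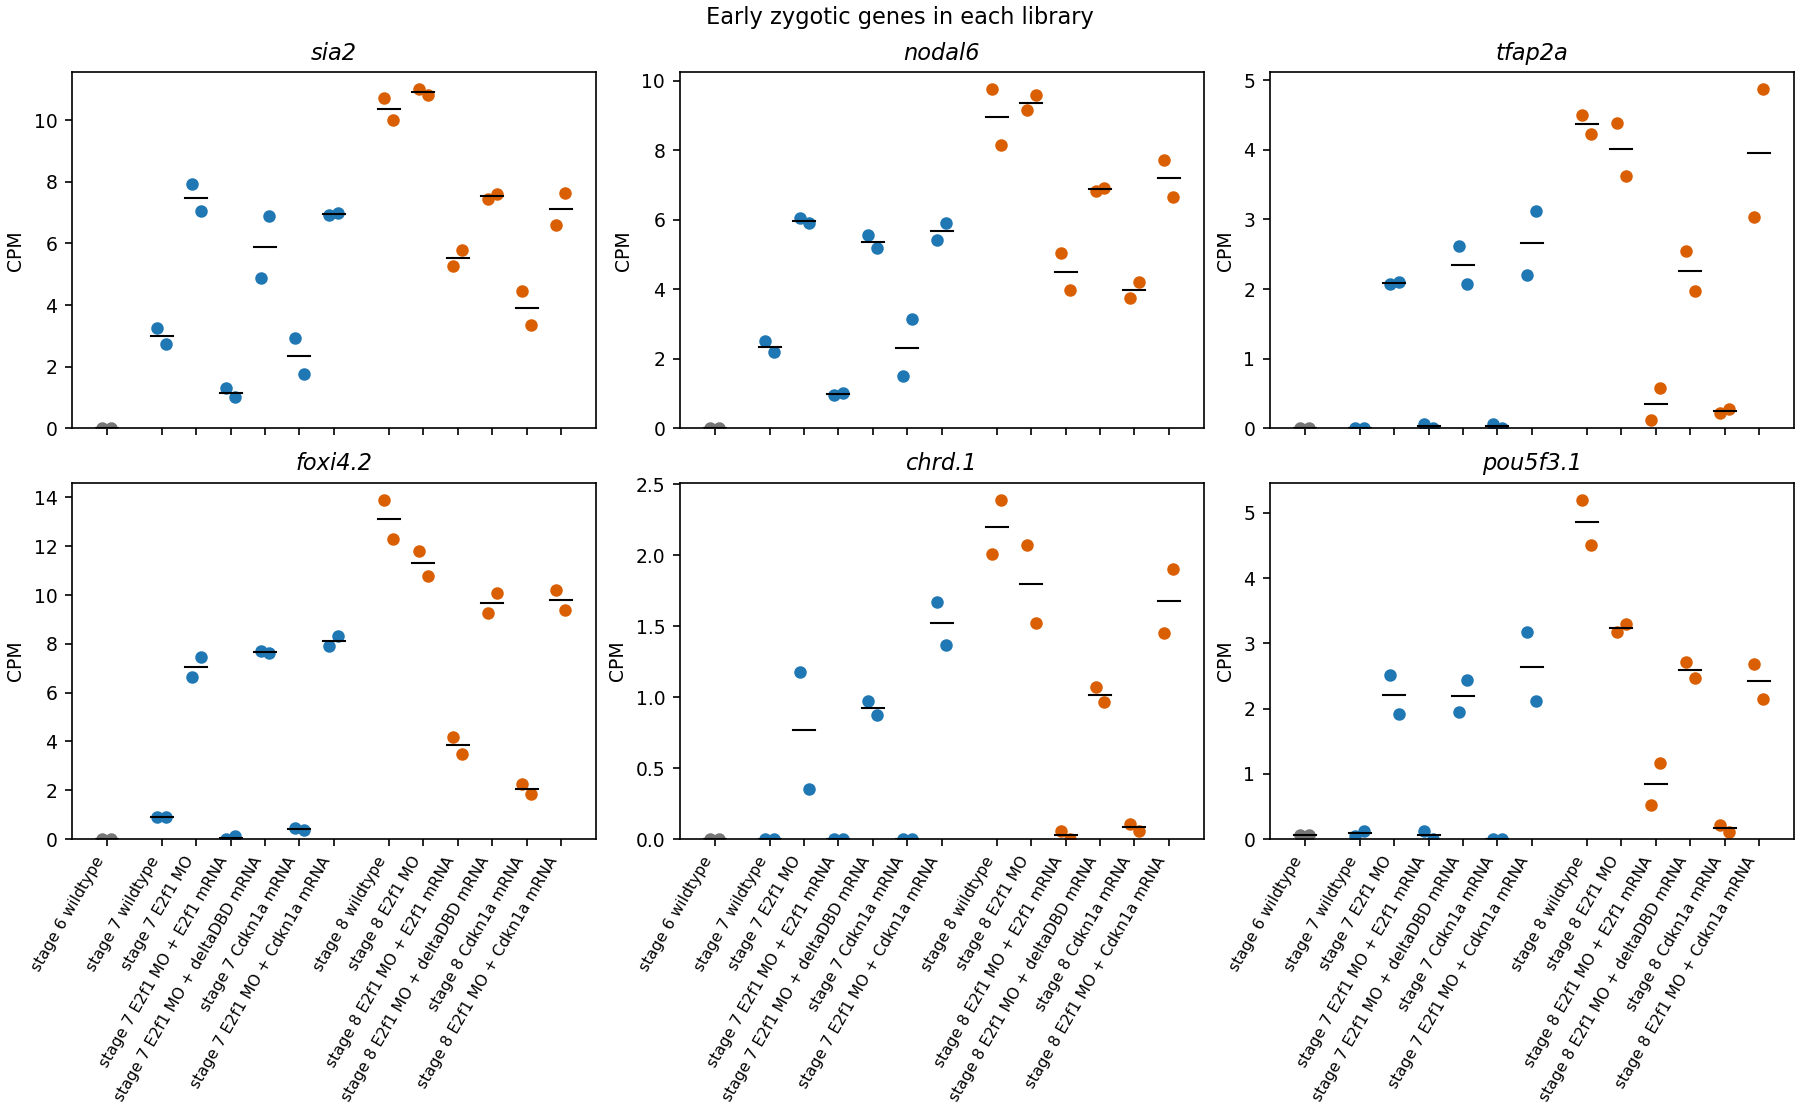
CPM of sia2, nodal6, tfap2a, foxi4.2, chrd.1 and pou5f3.1 in each library, on linear axes; dots are libraries, black lines group means, and grey, blue and orange mark stages 6, 7 and 8. tfap2a is at 0 CPM in stage 7 wildtype, at 2.09 CPM in stage 7 E2f1 MO embryos and at 4.37 CPM in stage 8 wildtype.

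E2f1 mRNA and deltaDBD mRNA were then compared in morphants of stage 7, which asks whether the DNA-binding form reverses the effect of the MO. The e2f1 transcript was far above wildtype with E2f1 mRNA (3010 ± 36 against 440 ± 9.2 CPM). Reversal of the MO effect is thus not told apart from an effect of excess E2f1. With E2f1 mRNA, 50 of 59 early zygotic genes were lower than with the MO alone and 1 was higher (adjusted over the list alone, 52 and 1), with a median of −3.62, or −2.75 with 12 genes at their bound (adjusted p = 5.16e-21, and adjusted p = 5.4e-07 with an estimated correlation). mix1, a mesendoderm homeobox gene, was at least 43.8-fold lower, the ectodermal gene foxi1 at least 42-fold and the receptor gene lpar6 at least 23-fold. ventx2.2 was at 0.399 ± 0.027 against 21.2 ± 1.6 CPM (−5.70 ± 0.22), foxi4.2 102-fold lower (counting interval 31.3 to 948), stx19 97-fold (21.1 to 4760) and rhov 143-fold (31.2 to 6980). Some transcripts that the MO had lowered were higher: cks2 by 1.49 ± 0.13, dnmt1 by 1.04 ± 0.034, grip2 by 1.0 ± 0.060 and top2a by 0.99 ± 0.045. So was inpp5j, by 1.85 ± 0.17, but it also rose with deltaDBD mRNA and with Cdkn1a mRNA in morphants (below). With E2f1 mRNA, slc5a5 (3.05 ± 0.43), adcy8 (1.73 ± 0.39) and ifrd1 (1.40 ± 0.078) were higher as well. Mitotic genes rose, 26 of 42 against 9 down (adjusted over the list alone, 27 and 9; adjusted p = 2.22e-05, and adjusted p = 0.00184 with an estimated correlation), and so did RNA polymerase II genes, 28 of 48 against 6 down (adjusted p = 0.00508, and adjusted p = 0.0274 with an estimated correlation). In this comparison 5849 genes differed, 2892 higher and 2957 lower.

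With deltaDBD mRNA in place of E2f1 mRNA, almost nothing differed from the MO alone at stage 7. The 4 calls were e2f1 itself (2.31 ± 0.039), inpp5j (1.77 ± 0.18), aff2 (−2.25 ± 0.37, adjusted p = 0.0037) and the galactosyltransferase gene b4galt1.1 (−1.05 ± 0.20, adjusted p = 0.028). Calls numbered 33 with only the stage 7 libraries in the fit, 16 without stage 8 E2f1 MO replicate 2 and 21 without the count filter. DESeq2 called 3 genes and 635 passed an unadjusted p of 0.05. aff2 lost its call without stage 7 E2f1 MO + deltaDBD mRNA replicate 1 (adjusted p = 0.85) and without stage 7 E2f1 MO replicate 2 (0.11). b4galt1.1 lost it in DESeq2 (0.12) and without any one of the 4 libraries (0.34 to 0.76). None of the 59 early zygotic genes was called by edgeR or by DESeq2, 2 up and 1 down passed an unadjusted p of 0.05, and their median was −0.11 (adjusted p = 0.706).

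Set against each other at stage 7, embryos with E2f1 mRNA and those with deltaDBD mRNA differed in 5998 genes, 2914 higher and 3084 lower. foxi1 was at least 39.8-fold lower with E2f1 mRNA, mix1 at least 36.8-fold and the homeobox gene ventx3.1 at least 22.1-fold. foxi4.2 was 112-fold lower (counting interval 34.1 to 1030), and sox2, a gene of the neural plate, fell by 5.91 ± 0.32. slc5a5 (2.61 ± 0.42), aff2 (2.44 ± 0.37) and plbd2 (1.32 ± 0.072) were higher, and adcy8 (1.49 ± 0.38) was higher except without stage 7 E2f1 MO + deltaDBD mRNA replicate 2 (adjusted p = 0.089). Of the early zygotic genes 49 fell and 1 rose, also when adjusted over the list alone (median −3.51, or −2.76 with 12 genes at their bound; adjusted p = 1.57e-19, and adjusted p = 7.88e-07 with an estimated correlation). Mitotic genes rose in 25 of 42 cases and fell in 8 (adjusted p = 0.000116, and adjusted p = 0.00332 with an estimated correlation).

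In the early zygotic and mitotic lists, stage 7 embryos with the MO and E2f1 mRNA were not back at the wildtype level but beyond it. The 40 genes lowered 1.5-fold or more by the MO at both stages, chosen after the data were seen, stayed below it. Their median was 64.1% of wildtype at stage 7, against 50.8% with the MO alone, low by selection. The first zygotic genes were lower: znf33b at −2.19 ± 0.38, nodal3.1 at −1.73 ± 0.29, znf33a at −1.71 ± 0.25, hes2 at −1.71 ± 0.34, znf470 at −1.59 ± 0.20 and znf350 at −1.46 ± 0.22 on the log2 scale. Of the early zygotic list 13 genes fell and 1 rose, also when adjusted over the list alone (median −0.75, or −0.27 with 13 genes at their bound; adjusted p = 3.94e-05, and adjusted p = 0.00122 with an estimated correlation). Mitotic genes were higher, 17 of 42 against 3 lower (adjusted over the list alone, 19 and 3; adjusted p = 0.000759, and adjusted p = 0.00716 with an estimated correlation), with top2a at 0.31 ± 0.044. Here 1678 genes differed, 879 higher and 799 lower. The count was smaller without any one of the 4 libraries, 763 and 527 without the first and second library of the injected group and 869 and 550 without those of wildtype. It was larger with only the stage 7 libraries in the fit (3004) and without stage 8 E2f1 MO replicate 2 (2858).

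Cdkn1a mRNA alone made mostly small changes at stage 7. cdkn1a was 81-fold higher than in wildtype (6.34 ± 0.093), 612 genes were called, 249 higher and 363 lower, and 7 rose and 8 fell by 2-fold or more. The median size of the called changes was 0.20. The early zygotic list did not move, with sox11 (0.25 ± 0.051, adjusted p = 0.0048) its 1 call (adjusted p = 0.178 for the list). Many of its genes had not yet risen in wildtype at stage 7, so a fall in them could hardly show. Of the 23 early risers in the chromosome 6 span, 6 were lower and none higher (median −0.83), and znf470 was lower (−1.08 ± 0.18). Mitotic genes were slightly lower, 14 of 42 against 1 higher (adjusted over the list alone, 17 and 2; median −0.08; adjusted p = 0.0026, and adjusted p = 0.0155 with an estimated correlation), with top2a at −0.31 ± 0.045 and smc4 at −0.21 ± 0.035. The remaining rises, of c5orf63 (1.14 ± 0.32), cyp3a4.3 (1.12 ± 0.28), meis2 (1.1 ± 0.24) and cds1 (0.95 ± 0.27), were lost without stage 7 wildtype replicate 1 (adjusted p = 0.22, 0.17, 0.064 and 0.20). The count depended on the libraries used. It was 43 and 143 without the first and second Cdkn1a mRNA library and 87 and 149 without those of wildtype. It was 1892 with only the stage 7 libraries in the fit and 1726 without stage 8 E2f1 MO replicate 2.

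In morphants, adding Cdkn1a mRNA at stage 7 left the zygotic genes where the MO had put them. None of the 59 was called against the MO alone by edgeR or by DESeq2, 2 up and 4 down passed an unadjusted p of 0.05, and their median was 0.06 (adjusted p = 0.907). Some transcripts that the MO had lowered were higher: inpp5j by 1.98 ± 0.17, the enolase gene eno1 by 1.52 ± 0.17, arpc3 by 1.5 ± 0.15 and cops6 by 1.39 ± 0.12. Maternal oocyte genes rose, 13 of 56 with none down (adjusted over the list alone, 23 and 1; adjusted p = 1.6e-07, and adjusted p = 0.0274 with an estimated correlation), among them ddx25 (0.38 ± 0.049), velo1 (0.25 ± 0.034) and dazl (0.36 ± 0.052). ankrd63 was lower (−0.85 ± 0.15). The 180 calls, 144 higher and 36 lower, became 61 and 88 without the first and second library with Cdkn1a mRNA and 67 and 96 without those of the MO alone. There were 792 with only the stage 7 libraries in the fit, 667 without stage 8 E2f1 MO replicate 2 and 371 without the count filter.

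Against Cdkn1a mRNA alone, the MO with Cdkn1a mRNA raised the zygotic genes at stage 7 much as the MO had done against wildtype: 49 of 59 rose and none fell (adjusted over the list alone, 50 and 2; median 3.33, or 2.94 with 7 genes at their bound; adjusted p = 6.82e-50, and adjusted p = 1.07e-08 with an estimated correlation). stx19 was at least 49.8-fold higher, fgf8 at least 30.1-fold, pou5f3.1, a relative of the pluripotency factor Oct4, at least 29.2-fold, ventx1.1 at least 23.9-fold and lpar6 at least 23-fold. ventx2.2 rose from 1.11 ± 0.23 to 17.2 ± 0.80 CPM and admp from 0.152 ± 0.052 to 9.37 ± 0.26 CPM. The metal transporter gene slc39a8 was lower (−2.03 ± 0.34). Of 968 calls 637 were higher and 331 lower, and without any one of the 4 libraries there were 355 to 455. There were 2078 with only the stage 7 libraries in the fit and 1979 without stage 8 E2f1 MO replicate 2. The interaction of the 2 treatments at stage 7 was called for 135 genes, 87 up and 48 down, and for 57 to 74 without any one of the 8 libraries. It was called for 675 with only the stage 7 libraries, 569 without stage 8 E2f1 MO replicate 2 and 209 without the count filter. In the early zygotic list it called 1 gene, hoxd1 (−1.40 ± 0.36, adjusted p = 0.045), and did not move the list (adjusted p = 0.205). Maternal oocyte genes had a positive interaction in 9 of 56 cases (adjusted over the list alone, 16; adjusted p = 5.23e-12, and adjusted p = 0.006 with an estimated correlation), led by grip2 (0.73 ± 0.084) and ddx25 (0.55 ± 0.069). Set against wildtype, embryos with both treatments differed in 3997 genes (2506 without stage 7 wildtype replicate 1), and 46 of the 59 early zygotic genes were higher and 1 lower (adjusted over the list alone, 51 and 1; median 2.15; adjusted p = 5.84e-27, and adjusted p = 1.49e-07 with an estimated correlation).

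At stage 8 the morphants no longer differed from wildtype in the zygotic list. gadd45g was higher (0.70 ± 0.17, adjusted p = 0.012) and admp lower (−0.41 ± 0.12, adjusted p = 0.046), and the median of the 59 genes was −0.05 (adjusted p = 0.907; adjusted over the list alone, 1 up and 0 down). The change of the MO effect between the stages was itself tested: 39 of the 59 genes had a smaller effect at stage 8 and 1 a larger one (adjusted over the list alone, 47 and 1; median −2.26; adjusted p = 1.37e-25, and adjusted p = 1.88e-07 with an estimated correlation). In all, 2080 genes were called there, and 1301 to 3471 without any one of the 8 libraries. Genes lower in stage 8 morphants were inpp5j, at 0.187 ± 0.0054 against 7.57 ± 0.12 CPM (−5.29 ± 0.32), fam83c (−2.09 ± 0.31), arpc3 (−1.98 ± 0.14), cars2, a mitochondrial tRNA synthetase gene (−1.97 ± 0.27), tmem203 (−1.57 ± 0.19) and romo1 (−1.85 ± 0.40), the last at adjusted p = 0.057 without stage 8 wildtype replicate 1. plekhn1 (2.53 ± 0.35), lad1 (2.2 ± 0.28) and the palmitoyltransferase gene zdhhc13 (1.09 ± 0.094) were higher. grip2 was still lower (−0.77 ± 0.065) and the Cdk1 kinase gene pkmyt1 was lower (−0.58 ± 0.062). There were 556 calls, 221 higher and 335 lower.

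One library of this group stood apart. In stage 8 E2f1 MO replicate 2, long transcripts were low against replicate 1 (Spearman correlation of the difference with exon length −0.619 across genes, while no other pair passed 0.322 in size), and the pair differed more than any other (chi-square per degree of freedom 13.1, against 1.83 to 2.32). All contrasts came from 1 fit with pooled spread. The spread within this pair thus entered the tests of contrasts that do not use it and can lower their counts of calls. Medians of whole lists depended on this library: that of the 73 ribosomal protein genes in morphants against wildtype at stage 8 was 0.03 with both libraries and −0.12 without this one, that of the 53 oxidative phosphorylation genes 0.09 and −0.10, and that of the 38 chromatin genes −0.05 and 0.05. Counts rose without this library also where it was not compared, as from 612 to 1726 for Cdkn1a mRNA and from 1678 to 2858 for the MO with E2f1 mRNA, both against wildtype at stage 7. The count of 556 became 497 without this library, 3015 without replicate 1, and 267 and 202 without the first and second wildtype library. It was 205 with only the stage 8 libraries in the fit and 946 without the count filter.

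Morphants with E2f1 mRNA, the rescue group, again had low zygotic transcripts at stage 8. The MO alone had not raised the list at this stage, so this fall was no reversal of an MO effect on it. In this group e2f1 was at 2730 ± 19 CPM against 402 ± 2.7 CPM in wildtype, and an effect of excess E2f1 was not tested. Against the MO alone 40 of 59 genes were lower and none higher (adjusted over the list alone, 45 and 1; median −1.92; adjusted p = 2.2e-44, and adjusted p = 1.07e-08 with an estimated correlation); DESeq2 called 37 lower. xmc fell by 3.83 ± 0.59, lpar6 by 3.61 ± 0.44, rhov by 3.51 ± 0.23, tfap2a by 3.46 ± 0.41, stx19 by 3.46 ± 0.34 and the Wnt ligand gene wnt8a by 3.38 ± 0.37 on the log2 scale. inpp5j (5.56 ± 0.30), fam83c (1.91 ± 0.32) and map1b (1.70 ± 0.14) were higher, and so were grip2 (1.02 ± 0.064), top2a (0.43 ± 0.046) and dnmt1 (0.37 ± 0.034). Of 781 calls 405 were higher and 376 lower (340 and 386 with median-of-ratios size factors). That count was 356 and 374 without the first and second library of the rescue group, 3462 without replicate 1 of the MO group and 504 without its replicate 2. It was 402 with only the stage 8 libraries and 1240 without the count filter.

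At stage 8, embryos with deltaDBD mRNA did differ from those with the MO alone. Against the MO alone 133 genes were called, 69 higher and 64 lower (61 and 73 with median-of-ratios size factors). Besides inpp5j (4.65 ± 0.35) and e2f1 (2.37 ± 0.039), these included 10 of the 59 early zygotic genes, all lower (adjusted over the list alone, 23; median −0.52; adjusted p = 1.57e-11, and adjusted p = 1.58e-05 with an estimated correlation), such as id3 (−0.75 ± 0.097), klf17 (−0.57 ± 0.085) and ventx2.2 (−0.61 ± 0.099). The 133 calls became 32 and 38 without the first and second deltaDBD library and 2564 without replicate 1 of the MO group, and 88 genes were called by DESeq2. There were 53 with only the stage 8 libraries and 556 without the count filter. Of the 23 early risers in the chromosome 6 span, 15 were lower with deltaDBD mRNA (median −0.55). With Cdkn1a mRNA in stage 8 morphants, 19 were lower against the same MO group (median −0.67). Cdkn1a mRNA alone lowered all 23 at stage 8 (median −2.59), so it is no control for added mRNA. No group had an inert mRNA, so an effect of deltaDBD is not told apart from one of any added mRNA. The MO group itself had no call among these 23 genes against wildtype (median 0.07), which argues against that group as their source. For the other calls the MO group was not told apart either. E2f1 mRNA against deltaDBD mRNA, which does not use the MO group, gave 206 calls, 38 higher and 168 lower. There stx19 fell by 3.19 ± 0.34, lpar6 by 3.02 ± 0.47, foxd4l1.1 by 2.85 ± 0.27, tfap2a by 2.64 ± 0.45, wnt8a by 2.63 ± 0.40 and rhov by 2.56 ± 0.25, and 29 of the 59 early zygotic genes were lower with none higher (adjusted over the list alone, 41 and 0; median −1.38; adjusted p = 6.3e-45, and adjusted p = 1.07e-08 with an estimated correlation). map1b (0.89 ± 0.12), grip2 (0.74 ± 0.062) and the transcription factor gene myb (0.47 ± 0.087) were higher. Without deltaDBD replicate 2, or the first or second E2f1 mRNA library, there were 129, 122 and 117 calls, and 417 without stage 8 E2f1 MO replicate 2. Against wildtype of stage 8, embryos with E2f1 mRNA had 42 of the 59 genes lower and 1 higher (adjusted over the list alone, 47 and 1; median −2.17; adjusted p = 2.14e-44, and adjusted p = 1.07e-08 with an estimated correlation), with chrd.1 63.4-fold lower (counting interval 13.9 to 3190) and znf750 at −3.93 ± 0.53, among 741 calls (394 to 464 without any one of the 4 libraries, 470 with only the stage 8 libraries and 1439 without stage 8 E2f1 MO replicate 2).

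Cdkn1a mRNA alone had a large effect at stage 8. Of the 59 early zygotic genes 45 were lower than in wildtype and 1 was higher (adjusted over the list alone, 46 and 1; median −2.15; adjusted p = 3.34e-48, and adjusted p = 1.07e-08 with an estimated correlation). tat was 96.7-fold lower (counting interval 21.4 to 4840) and chrd.1 24.4-fold lower (8.75 to 131). pou5f3.1 was at 0.165 ± 0.075 against 4.85 ± 0.49 CPM (−4.81 ± 0.43), the sodium pump gene atp1b2 at −4.44 ± 0.58, stx19 at −4.29 ± 0.32 and fst at −4.17 ± 0.57. klf17 (−2.04 ± 0.094), ventx2.2 (−2.61 ± 0.12), admp (−3.39 ± 0.17) and sox2 (−2.97 ± 0.17) were lower too. Next to cdkn1a, at 53.2-fold, the rises included socs2, a cytokine signalling suppressor (3.05 ± 0.49), chn2 (2.01 ± 0.20), tiparp (1.81 ± 0.24) and rab3il1 (2.07 ± 0.44), the last at adjusted p = 0.062 without stage 8 wildtype replicate 1. fbxo43 (0.75 ± 0.041), grip2 (0.52 ± 0.059) and top2a (0.43 ± 0.046) were higher as well, and mitotic genes rose in 7 of 42 cases with none down (adjusted over the list alone, 10 and 0; median 0.05; adjusted p = 0.0023, and adjusted p = 0.0151 with an estimated correlation). There were 801 calls, 362 higher and 439 lower, and 408 to 477 without any one of the 4 libraries. There were 482 with only the stage 8 libraries and 1440 without stage 8 E2f1 MO replicate 2.

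The contrast between stages was tested here as well. The Cdkn1a mRNA effect differed between stages 7 and 8 for 785 genes, 471 up and 314 down, and 19 of the 59 early zygotic genes had a lower effect at stage 8 and 1 a higher one (adjusted over the list alone, 22 and 1; median −1.39; adjusted p = 2.72e-29, and adjusted p = 9.82e-08 with an estimated correlation). Mitotic genes went the other way, 16 of 42 up and 1 down (median 0.16; adjusted p = 0.00219 with an estimated correlation). Zygotic genes not yet risen at stage 7 could hardly fall there. Of the 23 early risers in the chromosome 6 span, 6 were already lower with Cdkn1a mRNA at stage 7. The count of 785 was 359 to 476 without 6 of the 8 libraries, and 527 and 526 without stage 8 Cdkn1a mRNA replicate 2 and stage 8 wildtype replicate 1. It rose to 1777 without stage 8 E2f1 MO replicate 2.

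In stage 8 morphants, few genes of the early zygotic list were called lower with Cdkn1a mRNA. Of the 23 early risers in the chromosome 6 span, however, 19 were lower than with the MO alone (median −0.67). Against the MO alone 5 of 59 were lower and none higher (adjusted over the list alone, 14 and 0; median −0.29; adjusted p = 4.27e-06, and adjusted p = 0.000513 with an estimated correlation), with id3 at −0.56 ± 0.097, ventx2.2 at −0.55 ± 0.10 and ventx2.1 at −0.66 ± 0.14. inpp5j (5.79 ± 0.30), fam83c (1.92 ± 0.32) and arpc3 (1.36 ± 0.15) were higher and lad1 lower (−2.09 ± 0.28). The 234 calls became 93 and 96 without the first and second library with Cdkn1a mRNA, and 2343 and 589 without the first and second of the MO alone. There were 126 with only the stage 8 libraries and 503 without the count filter. Against Cdkn1a mRNA alone, the MO with Cdkn1a mRNA raised 35 of the 59 genes and lowered none (adjusted over the list alone, 46 and 0; median 1.77; adjusted p = 3.5e-47, and adjusted p = 1.07e-08 with an estimated correlation). tat was 62.2-fold higher (counting interval 13.5 to 3110), and tfap2a was higher by 3.98 ± 0.44, pou5f3.1 by 3.79 ± 0.50, stx19 by 3.71 ± 0.34, sfrp2 by 3.69 ± 0.44 and the homeobox gene dlx5 by 3.56 ± 0.55 on the log2 scale, and chn2 fell (−1.17 ± 0.19), among 520 calls (272 to 300 without any one of the 4 libraries, 310 with only the stage 8 libraries and 1018 without stage 8 E2f1 MO replicate 2). The interaction of the 2 treatments at stage 8 was called for 815 genes, 496 up and 319 down, and was positive for 32 of the 59 and negative for none (adjusted over the list alone, 42 and 0; median 1.81; adjusted p = 6.91e-24, and adjusted p = 2.66e-07 with an estimated correlation). That count was 473 to 543 without stage 8 Cdkn1a mRNA replicate 1, either library with both treatments or stage 8 wildtype replicate 2, 2733 without replicate 1 of the MO group, 384 with only the stage 8 libraries and 539 by DESeq2.

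Embryos with both treatments were close to wildtype at stage 8, with 61 calls, 15 higher and 46 lower (20 to 38 without any one of the 4 libraries, 35 with only the stage 8 libraries, 201 without stage 8 E2f1 MO replicate 2 and 125 without the count filter). Apart from cdkn1a, zdhhc13 (0.68 ± 0.096), the transcription factor gene usf2 (0.32 ± 0.045) and fbxo43 (0.31 ± 0.041) were higher and znf470 was lower (−0.68 ± 0.077). Of the 23 early risers in the chromosome 6 span, 14 were lower and none higher (median −0.58), so these genes were not back at the wildtype level. In the early zygotic list 2 genes were lower and none higher (adjusted over the list alone, 18 and 1; median −0.39; adjusted p = 7.85e-08, and adjusted p = 0.000129 with an estimated correlation).

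**Figure D4:**
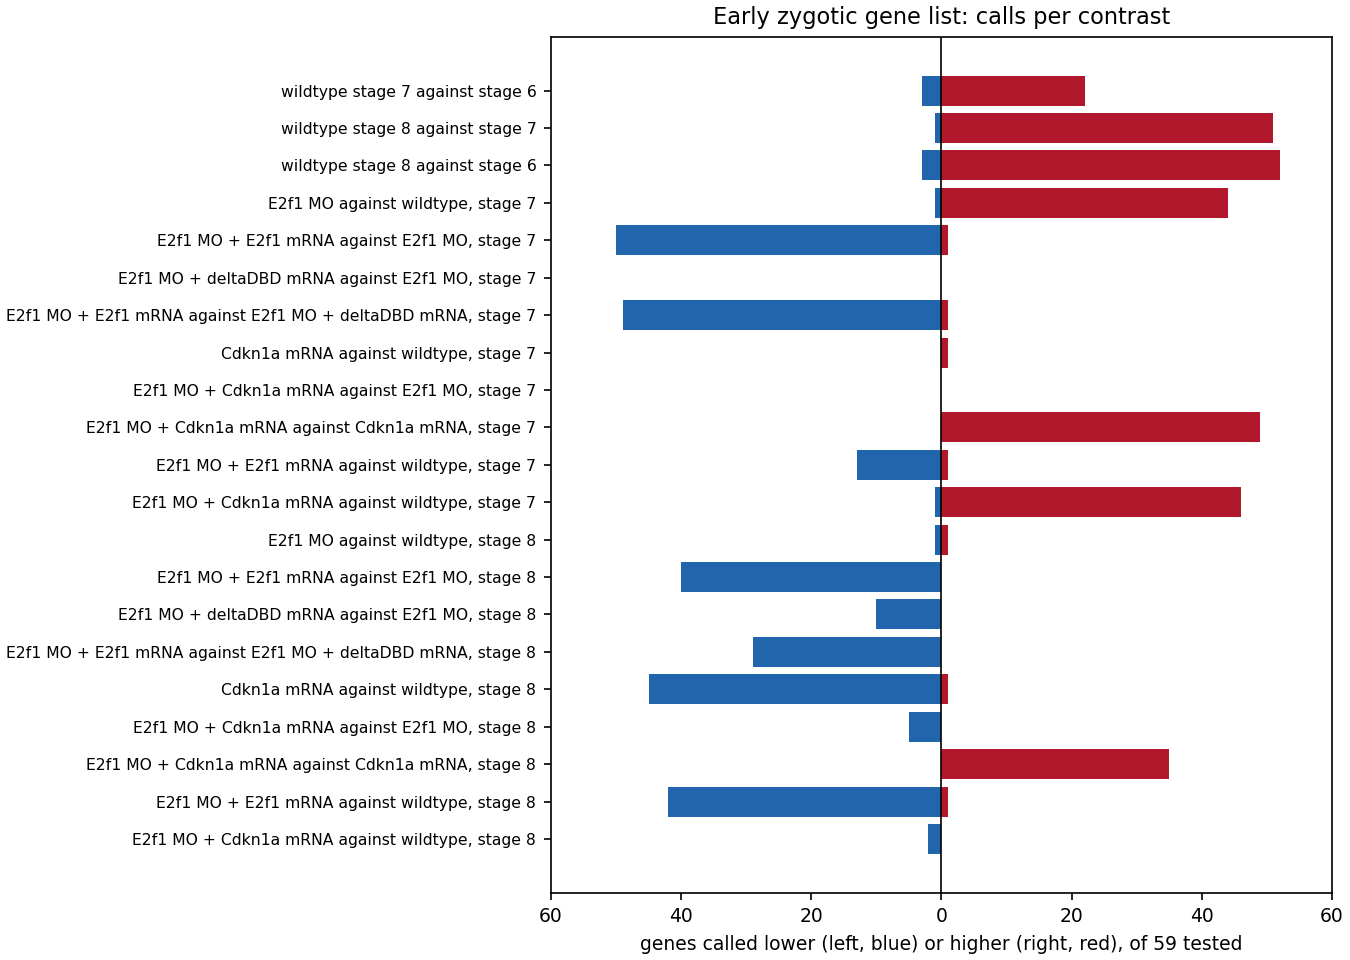
Number of the 59 early zygotic genes called in each comparison at adjusted p under 0.05; bars to the left (blue) count genes that were lower and bars to the right (red) genes that were higher. At stage 7 the MO against wildtype gives 44 higher, and at stage 8 Cdkn1a mRNA against wildtype gives 45 lower.

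The wildtype time course gave a measure for the injected embryos. Genes 2-fold or more higher (1707) or lower (299) in wildtype of stage 8 than of stage 6 were read at stage 7, where no library is shared with that list. In stage 7 morphants 740 of the rising genes were higher than in wildtype and 18 lower (median 0.30), and 149 of the falling genes were lower and 3 higher (median −0.35). E2f1 mRNA against deltaDBD mRNA gave the opposite, with 1301 of the rising genes lower and none higher (median −0.62) and 195 of the falling genes higher and none lower (median 0.49). Cdkn1a mRNA alone at stage 7 had 157 of the rising genes higher and 8 lower (median 0.16) and 79 of the falling genes lower and none higher (median −0.18). The median wildtype step from stage 7 to 8 was 0.48 for the rising genes. Their share of it with Cdkn1a mRNA, a least-squares slope in which large changes weigh most, was 3.12%. With a 4-fold list the rising genes had a median of 0.07 in this group and were no longer a call (adjusted p = 0.47). For stage 8 the list was genes that changed 2-fold or more between stages 6 and 7, of which 739 rose and 62 fell. Cdkn1a mRNA had 104 of the rising ones lower and 13 higher at stage 8 (median −0.07), E2f1 mRNA against deltaDBD mRNA 70 lower and 1 higher (median −0.15), and the MO against wildtype 31 lower and 8 higher (median −0.04). The last was not a call (adjusted p = 0.168), but it was one at −0.11 in the fit without stage 8 E2f1 MO replicate 2 (adjusted p = 3.33e-07), and without replicate 1 the median was 0.06. Of the falling ones, 9 were higher and 3 lower with Cdkn1a mRNA (adjusted p = 0.0821, but adjusted p = 0.0498 with an estimated correlation), 1 higher and 4 lower for E2f1 mRNA against deltaDBD mRNA (adjusted p = 0.82), and 2 higher and 2 lower for the MO (adjusted p = 0.594). They were lower as a list with the MO and Cdkn1a mRNA than with Cdkn1a mRNA alone, 6 lower and none higher (adjusted p = 0.00911, and adjusted p = 0.0072 with an estimated correlation). Their interaction at stage 8 was negative, 5 down and 1 up (adjusted p = 0.027, and adjusted p = 0.0189 with an estimated correlation). Both of these last calls were lost with a 4-fold list. That of the interaction was also lost with a replicate block and in the fit without stage 8 E2f1 MO replicate 2.

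Comparisons without a common library were set side by side. Of the genes called in stage 7 morphants against wildtype, 1392 that were higher were lower with E2f1 mRNA than with deltaDBD mRNA (392 for independent lists), and 1406 that were lower were higher there (363 for independent lists), with a correlation across genes of −0.762. At stage 8 the same pair had a correlation of 0.0282, with 19 genes lower with the MO and higher with E2f1 mRNA (0.988 for independent lists) and 2 the other way (2.88). The MO had like effects with and without Cdkn1a mRNA at stage 7, with 478 genes higher in both (81 for independent lists), 265 lower in both (41.2) and a correlation of 0.753. At stage 8 they shared 49 lower genes (5.72 for independent lists), and the correlation was −0.0779. There, 14 genes were higher with the MO alone and lower with it beside Cdkn1a mRNA (3.77 for independent lists, adjusted p = 4.24e-05). Cdkn1a mRNA with and without the MO shared 12 higher genes at stage 7 (2.78 for independent lists; correlation 0.0614) and 40 lower genes at stage 8 (3 for independent lists; correlation 0.143). At stage 8, 13 and 9 of their genes went in opposite directions (4.98 and 2.47 for independent lists; adjusted p = 0.0021 and 0.0012). The effect of E2f1 mRNA against deltaDBD mRNA shared 159 lower genes between stages 7 and 8 (40.2 for independent lists; correlation 0.583), and the MO effect 140 lower genes (41.7; correlation 0.0389). Of the MO calls 43 were lower at stage 7 and higher at stage 8 (27.5; adjusted p = 0.00378). For Cdkn1a mRNA against wildtype, 51 genes were lower at stage 7 and higher at stage 8 (10.2 for independent lists; correlation 0.131). These correlations are across genes, which are not independent replicates.

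Pairs that share control libraries were read with a simulation of unchanged groups. The MO against wildtype and E2f1 mRNA against the MO at stage 7 shared 1488 genes that rose and then fell and 1478 that fell and then rose (376 and 360 for independent lists). Their covariance was −0.446, against −0.0407 simulated. The MO and Cdkn1a mRNA at stage 7, both against wildtype, had a covariance of 0.0562 (0.0416 simulated) and shared 330 lower genes (45.2 for independent lists), and at stage 8 a covariance of 0.054 (0.0291 simulated). The MO and E2f1 mRNA pair at stage 8 had −0.0491 (−0.0336 simulated). The controls were not split, as each part would have held 1 library, so part of each excess may come from them. The mean simulated number of shared calls was 0, but the groups were simulated unchanged, so hardly any call could be shared. Neither this number nor those for independent lists can show how many shared calls come from common controls.

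The other lists moved little. Nodal, Wnt, BMP and FGF genes were 14 higher and 2 lower of 37 in stage 7 morphants against wildtype (adjusted over the list alone, 15 and 2; adjusted p = 0.000862, but adjusted p = 0.189 with an estimated correlation), and histone genes 7 lower and none higher of 20 (adjusted over the list alone, 8 and 0; adjusted p = 0.0018, but adjusted p = 0.168 with an estimated correlation). Ribosomal protein genes were 13 lower and 1 higher of 73 there (adjusted p = 0.00941, but adjusted p = 0.918 with an estimated correlation). For stage 8 morphants the oxidative phosphorylation list gave 1 call of 53 (adjusted p = 0.00408, but adjusted p = 0.797 with an estimated correlation). Chromatin genes fell in 14 of 38 cases and rose in 4 from wildtype stage 7 to 8 (adjusted p = 0.00848, but adjusted p = 0.723 with an estimated correlation). The E2F and RB family, p53 pathway, apoptosis, innate immune, stress, differentiated tissue, testis and follicle lists gave no call in any comparison, with smallest adjusted p of 0.0967, 0.16, 0.203, 0.729, 0.104, 0.365, 0.295 and 0.193. Single members did move: in stage 7 morphants 3 of 23 E2F and RB family genes were higher and 2 lower, 2 of 26 p53 pathway genes higher and 4 lower, and 6 of 27 stress genes higher and 2 lower. Genes of the mitochondrial genome are absent from the table.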

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

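All tests of explanations in this part were chosen after the results were seen. Each result below was picked out because an effect differed between 2 groups or 2 stages in a test of the difference itself.

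The MO effect differed between stages for 2080 genes, and the median difference of the early zygotic genes was −2.26. The stage 7 morphants held zygotic transcripts early, so their state was set against the wildtype course. Embryos injected with Cdkn1a mRNA alone had a median of −0.04 at stage 7 and so showed no rise. Injection itself was still not excluded, since Cdkn1a mRNA lowered zygotic genes at stage 8 and could hide a rise. No group had a control MO. Normalization was not put to a test. Median-of-ratios size factors moved the median of no contrast by more than 0.024, but like TMM they take most transcripts as unchanged. A change in the total amount of polyadenylated RNA was thus not excluded. A later point of the wildtype course at collection was not excluded: by least-squares slope, in which large changes weigh most, stage 7 morphants had covered 80.7% of the wildtype step from stage 7 to 8 for rising genes and 39.1% for falling genes, against at most 4.85 and 12.1% in simulated unchanged groups (21.8% for falling genes with Cdkn1a mRNA). By medians they had moved 0.30 of 0.48 and −0.35 of −0.58. Of the rising genes, 66 had no count in at least 1 of the 2 groups compared. Their fitted values are no bounds, and how far they shape the 80.7% was not tested. The labels give no time of collection, so a faster course, a later collection and a lost repression by E2f1 may each fit, and no test here separates them.

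The Cdkn1a effect differed between stages for 785 genes, with a median of −1.39 for the early zygotic genes, and the interaction at stage 8 was called for 815 genes, with a median of 1.81. For the low zygotic transcripts with Cdkn1a mRNA at stage 8, an earlier point of the course was not excluded, since these embryos had gone back 74.7% of the step for falling genes (median 0.26 of 0.58), against at most 29.1% in simulated groups with the same shared wildtype libraries. Every other injected stage 8 group passed that limit as well (40.8 to 57%), but for rising genes the slope was 61.3% with Cdkn1a mRNA and 51% with E2f1 mRNA in morphants (medians −0.11 and −0.20 of −0.48), against 3.97, 13.8 and 9.87% with the MO alone, deltaDBD mRNA and both treatments (at most 2.12% in simulated groups). For the weaker effect in morphants, a loss of most of the cdkn1a mRNA was excluded, as it reached 83.5% of the level without MO at stage 8. Whether the remaining difference matters was not tested, and Cdkn1a protein was not measured. A slower course with Cdkn1a mRNA and a need for E2f1 in that delay may both fit and were not separated.

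Stage 8 E2f1 MO replicate 2 stood apart from its replicate. Its low long transcripts define the pattern and were not tested for a cause. A wildtype library under this label was excluded, since 34 genes low in stage 7 morphants and not falling in wildtype from stage 7 to 8 had a median of −0.90 against stage 8 wildtype in this library (−1.05 in replicate 1) and 33 of them were lower. No biological explanation was tested.

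The interaction of MO and Cdkn1a mRNA at stage 7 was called for 135 genes. Large positive values were inpp5j 1.42, eno1 1.39, cops6 1.39, slc25a34 1.32 and arpc3 1.31. The largest negative values were slc39a8 −2.17, plekhn1 −2.07, slc44a3 −1.59, hoxd1 −1.40, ptpn13 −1.33 and slc38a2 −1.30. At stage 8 the interaction was largest for tat 6.34, chrd.1 4.52, atp1b2 4.52, inpp5j 4.51, stx19 4.38 and pou5f3.1 4.38, and among the lowest were lad1 −3.03, plekhn1 −3.0, rab3il1 −2.43, socs2 −2.24 and chn2 −2.19.

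Between stages the MO effect rose most for tbx6 1.45, lad1 1.33, tcp10l2 1.32, htr1e 1.28, cks2 1.25 and nxpe3l.6 1.2. It was lowest for tfap2a −8.31, tat −8.15, fst −7.88, rhov −7.55, xmc −7.47 and znf750 −7.13. The Cdkn1a effect rose most for adcy8 1.85, dmbx1 1.74, tcp10l2 1.63, neurog1 1.55, chn2 1.5 and slc35g1 1.5. It was lowest for tat −11.05, irx1 −6.42, grhl3 −4.09, foxd4l1.1 −3.96, eomes −3.02 and prdm16 −2.77. Where a group had no count, these fitted values are no bounds, and many of these calls were lost when 1 library was left out. The rankings hold only among the reported genes that met the naming rule.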

How the results depend on the processing

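The calls depended more on the set of libraries than on scaling. Of the 25 counts of changed genes, all stayed within 1.5 times with median-of-ratios size factors, with e2f1 and cdkn1a left out and with a replicate block, 23 with DESeq2 and 17 without the filter. Among named genes DESeq2 kept 1821 calls or non-calls, with 8 gained and 114 lost. Where 1 library was left out, the lone sample of its group was assumed to vary like the other groups; 8032 gene results stayed calls or non-calls, 167 gained and 1197 lost a call. With an estimated correlation 65 of 450 list results lost their call. Except where stated, the cause of a change was not tested. Stage is given in brackets, and rescue means the MO with E2f1 mRNA.

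In a fit leaving stage 8 E2f1 MO replicate 2 aside, chosen after the data were seen, these counts moved by more than 1.5 times: Cdkn1a against wildtype (7) 1726, Cdkn1a against wildtype (8) 1440, Cdkn1a effect between stages 1777, MO with Cdkn1a against Cdkn1a (7) 1979, MO with Cdkn1a against Cdkn1a (8) 1018, MO with Cdkn1a against MO (7) 667, MO with Cdkn1a against MO (8) 589, MO with Cdkn1a against wildtype (8) 201, deltaDBD against MO (7) 16, rescue against deltaDBD (8) 417, rescue against MO (8) 504, rescue against wildtype (7) 2858, rescue against wildtype (8) 1439, interaction (7) 569. With only the libraries of the stages compared they were Cdkn1a against wildtype (7) 1892, Cdkn1a against wildtype (8) 482, MO with Cdkn1a against Cdkn1a (7) 2078, MO with Cdkn1a against Cdkn1a (8) 310, MO with Cdkn1a against MO (7) 792, MO with Cdkn1a against MO (8) 126, MO with Cdkn1a against wildtype (8) 35, deltaDBD against MO (7) 33, deltaDBD against MO (8) 53, rescue against MO (8) 402, rescue against wildtype (7) 3004, rescue against wildtype (8) 470, MO against wildtype (8) 205, interaction (7) 675, interaction (8) 384. Without the count filter, where more genes are tested, they were MO with Cdkn1a against MO (7) 371, MO with Cdkn1a against MO (8) 503, MO with Cdkn1a against wildtype (8) 125, deltaDBD against MO (7) 21, deltaDBD against MO (8) 556, rescue against MO (8) 1240, MO against wildtype (8) 946, interaction (7) 209. DESeq2 gave deltaDBD against MO (8) 88, interaction (8) 539.

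Leaving out 1 library at a time gave these ranges of counts: Cdkn1a against wildtype (7) 43 to 149, Cdkn1a against wildtype (8) 408 to 477, Cdkn1a effect between stages 359 to 527, MO with Cdkn1a against Cdkn1a (7) 355 to 455, MO with Cdkn1a against Cdkn1a (8) 272 to 300, MO with Cdkn1a against MO (7) 61 to 96, MO with Cdkn1a against MO (8) 93 to 2343, MO with Cdkn1a against wildtype (7) 2506 to 2898, MO with Cdkn1a against wildtype (8) 20 to 38, deltaDBD against MO (7) 2 to 3, deltaDBD against MO (8) 32 to 2564, rescue against deltaDBD (8) 117 to 148, rescue against MO (8) 356 to 3462, rescue against wildtype (7) 527 to 869, rescue against wildtype (8) 394 to 464, MO against wildtype (7) 1922 to 2445, MO against wildtype (8) 202 to 3015, MO effect between stages 1301 to 3471, interaction (7) 57 to 74, interaction (8) 473 to 2733. The high ends of the stage 8 and between-stage results that use the MO group came from leaving out stage 8 E2f1 MO replicate 1, so that replicate 2 alone stood for its group.

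Wildtype genes changed 2-fold from stage 6 to 7 are called first risers and fallers here, and those from stage 6 to 8 course risers and fallers. The fit without that replicate 2 gave first risers in MO with Cdkn1a against MO (8) 0.13 (call gained), first risers in deltaDBD against MO (8) 0.08 (test direction reversed), first risers in MO against wildtype (8) −0.11 (call gained), first fallers in interaction (8) 0.02 (call lost). The 4-fold lists, which hold fewer genes, gave first risers in MO with Cdkn1a against MO (8) −0.39 (test direction reversed), first risers in MO with Cdkn1a against wildtype (8) −0.43 (call gained), first risers in deltaDBD against MO (8) −0.48 (call gained), course risers in Cdkn1a against wildtype (7) 0.07 (call lost), course risers in MO with Cdkn1a against MO (7) 0.09 (call lost), course risers in deltaDBD against MO (7) 0.02 (call lost), course risers in interaction (7) 0.05 (test direction reversed), first fallers in MO with Cdkn1a against Cdkn1a (8) −0.31 (call lost), first fallers in interaction (8) −0.39 (call lost), course fallers in MO with Cdkn1a against MO (7) 0.02 (call lost), course fallers in deltaDBD against MO (7) 0.02 (call lost). Median-of-ratios size factors gave first fallers in Cdkn1a against wildtype (8) 0.05 (call gained). With an estimated correlation, course risers in deltaDBD against MO (7) and in interaction (7) lost their calls (camera adjusted p = 0.284 and 0.288). With 1 library left out the medians ranged as follows: first risers in MO with Cdkn1a against MO (8) −0.06 to 0.13, first risers in deltaDBD against MO (8) −0.12 to 0.08, first risers in MO against wildtype (8) −0.11 to 0.06, first risers in interaction (8) 0.08 to 0.27, course risers in deltaDBD against MO (7) 0.02 to 0.08, course risers in interaction (7) −0.09 to −0.02, first fallers in Cdkn1a against wildtype (8) 0.02 to 0.18, first fallers in MO with Cdkn1a against Cdkn1a (8) −0.19 to −0.06, first fallers in interaction (8) −0.17 to 0.00, course fallers in MO with Cdkn1a against MO (7) −0.05 to −0.03.

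The direction of the camera test was reversed for these lists (medians given) in the fit without stage 8 E2f1 MO replicate 2: chromatin regulators in MO with Cdkn1a against MO (8) −0.07 instead of 0.05, chromatin regulators in deltaDBD against MO (8) −0.01 instead of 0.09, chromatin regulators in MO against wildtype (8) 0.05 instead of −0.05, cytosolic ribosomal proteins in deltaDBD against MO (8) 0.08 instead of −0.05, cytosolic ribosomal proteins in rescue against MO (8) −0.01 instead of −0.14, cytosolic ribosomal proteins in MO against wildtype (8) −0.12 instead of 0.03, cytosolic ribosomal proteins in interaction (8) 0.12 instead of −0.06, nuclear oxidative phosphorylation genes in MO with Cdkn1a against MO (8) 0.12 instead of −0.04, nuclear oxidative phosphorylation genes in deltaDBD against MO (8) 0.08 instead of −0.07, nuclear oxidative phosphorylation genes in MO against wildtype (8) −0.10 instead of 0.09.

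Overlaps at an unadjusted p under 0.01 moved by more than 1.5 times for those in the opposite direction, Cdkn1a against wildtype (7) with Cdkn1a against wildtype (8) 101 instead of 56, in the opposite direction, MO with Cdkn1a against wildtype (7) with MO with Cdkn1a against wildtype (8) 118 instead of 29, in the opposite direction, MO against wildtype (8) with rescue against deltaDBD (8) 65 instead of 21, in the opposite direction, MO against wildtype (8) with rescue against MO (8) 346 instead of 174, in the same direction, Cdkn1a against wildtype (7) with MO with Cdkn1a against MO (7) 93 instead of 14, in the same direction, Cdkn1a against wildtype (8) with MO with Cdkn1a against MO (8) 100 instead of 55, in the same direction, MO with Cdkn1a against Cdkn1a (7) with MO with Cdkn1a against Cdkn1a (8) 487 instead of 323, in the same direction, MO with Cdkn1a against MO (7) with MO with Cdkn1a against MO (8) 184 instead of 78, in the same direction, deltaDBD against MO (7) with deltaDBD against MO (8) 12 instead of 2, in the same direction, rescue against deltaDBD (7) with rescue against deltaDBD (8) 393 instead of 192, in the same direction, rescue against wildtype (7) with rescue against wildtype (8) 407 instead of 268, in the same direction, MO against wildtype (7) with Cdkn1a against wildtype (7) 867 instead of 527, in the same direction, MO against wildtype (8) with Cdkn1a against wildtype (8) 216 instead of 94, in the same direction, MO against wildtype (8) with MO with Cdkn1a against Cdkn1a (8) 96 instead of 61. DESeq2 calls gave an overlap in the same direction of 52 instead of 94 for the MO and Cdkn1a at stage 8, both against wildtype.

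By their labels the replicates share only a number. Across 78 pairs of groups the correlation of same-numbered deviations ran from −0.246 to 0.209 (median 0.0457), and 13 passed 0.1. Such weak correlations neither show nor exclude a shared clutch or batch, so whether the numbers pair the libraries is not known. A replicate block moved no count of calls by more than 1.5 times, changed 4 list results to calls and 1 from a call, 26 and 4 gene results likewise, and gave a median of −0.07 instead of −0.10 for first fallers in interaction (8), whose call was lost.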

Other observations

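The tests in this part were chosen after the results were seen. A set of transcripts was low in morphants at both stages. There were 40 genes lower by 1.5-fold or more in E2f1 MO embryos than in wildtype at both stages and 6 higher. The low ones include arpc3 of the Arp2/3 complex, cops6 of the signalosome, the cyclophilin gene ppia, the enolase gene eno1, inpp5j and tmem203. Their median level was 50.8% of wildtype at stage 7 and 48.4% at stage 8, low by selection. It was 64.1 and 69% with E2f1 mRNA, 55.5 and 61.6% with deltaDBD mRNA, 90.4 and 78.3% with Cdkn1a mRNA in morphants, and 103 and 97.7% with Cdkn1a mRNA alone.

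The clustering of early risers on chromosome 6 lay mostly in the array of zinc finger genes, which held 23 of the 29. Its adjusted p of 3.26e-10 comes from Fisher's exact test, which takes these genes as independent. A pair of further overlaps joined the stages. Of the genes higher in stage 7 morphants, 277 were lower with Cdkn1a mRNA at stage 8 (55.9 for independent lists; correlation −0.652). Of those lower with Cdkn1a mRNA at stage 8, 316 were lower with E2f1 mRNA in stage 7 morphants (101 for independent lists; correlation 0.631).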
